A study of Homo sapiens with 12 samples.

How the data were processed

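Total RNA from 12 samples was measured on Illumina bead arrays, with biotinylated cRNA prepared by a linear amplification kit, per the labels' protocols. The samples were 3 human cell lines, each under 2 treatments, with 2 arrays in each of the 6 groups; group and replicate number were taken from the cell line, treatment and replicate labels. No untreated sample was analysed here.

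The values used were the deposited table of log2 expression, which pairs 20545 gene symbols with the 12 samples, and they were read as log2 from their range, not from a stated unit. The submitters' processing notes name limma; its version, the background correction and the normalization are not given in the sources used here. Over values above 0 the array medians lay between 8.04 and 8.62; as listed, zeros included, they were 7.46 and 7.48 on the HCT116 replicate 2 arrays against 8.48 to 8.62 elsewhere. Whether the arrays were scaled to each other before deposit was not tested. HCT116 has values for 17290 symbols and HL60 and SNU398 for 19402, with 16147 in both sets, 1143 in HCT116 alone and 3255 in the other lines alone. Both HCT116 replicate 2 arrays list exactly 0 for the same 4938 genes, 28.6% of their symbols, against 9 genes on each replicate 1 array; these zeros were treated as not measured, because no other value on these arrays came near 0. Of all genes, 12349 were above 0 on all 12 arrays. A further table of bead-level signals and detection p-values, with 44 columns for 11 arrays, names its arrays in a way that matches no sample's labels, and it was not used.

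That table had been meant for background correction, a detection filter and a choice of probe per gene. In its place the deposited log2 values were tested as they stood, with 1 value per symbol and no filter on low values. This, and the reading of zeros as not measured, was decided after the data were seen. Of the symbols, 15305 matched a gene in a table of human gene names, 12993 of them under the current symbol, and 5240 did not match; symbols are printed as the deposited table gives them. Gene lists were matched through current and older symbols, which found 846 of 932 list genes.

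The groups, contrasts, unpaired limma fit, gene lists, rule for named genes and a block for the replicate number as an alternative were fixed before the data were examined. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) was fitted to the 6 group means over all 12 arrays, with 6 residual degrees of freedom for a gene measured on every array. The contrasts were the combination minus 5-Aza-CdR alone within each line, the mean of these over the 3 lines, and the differences between lines, as a moderated F test and as each difference. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg within a contrast). Tests were two-sided.

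The replicate numbers of the labels pair the arrays. Deviations from the group means of arrays with the same number correlated across genes by Pearson r of 0.907 in HCT116, 0.883 in HL60 and 0.841 in SNU398, over 0.1 in each of the 3 lines. That limit uses no calls, but the correlations and the first counts of calls were seen together. The alternative with the replicate number within a line as a block is the same as a fit to the 6 pair differences, with 3 residual degrees of freedom. A fit to the 2 pair differences of 1 line alone, with 1 residual degree of freedom and a spread moderated over genes, was added after seeing the data. It was chosen when its calls had been seen beside the absence of calls in the unpaired fit, so its adjusted p do not account for that choice. Where a fit to the pairs of 1 line is named, this is meant.

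There were 32 gene lists, tested where at least 5 members were measured, covering interferon response and innate sensing, antigen presentation, germline genes, chromatin and DNA methylation, stress, metabolism, proliferation and cell type markers. Each was tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists of a contrast. Member counts are given over all genes tested and adjusted over the list alone.

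The rule for named genes takes, per line, the 10 largest rises and the 10 largest falls among called genes whose combination arrays all lie beyond the 5-Aza-CdR arrays. For the average it takes the 10 largest of each direction among called genes with the same sign in all 3 lines, and for differences between lines the 10 smallest p. It adds up to 4 members per list with the smallest p in the average and in each line where camera called the list, DNMT1 and the TET genes, and the 5 smallest p where nothing was called. Symbols of uncharacterised loci and XIST are passed over, and other X-linked genes are kept. Because the unpaired fit called no gene, the part on rises and falls was applied to the fit to the pairs of 1 line, a choice made after seeing the data. Genes at least 2-fold apart in both pairs of a line, other members of called lists and the genes called in 2 lines were named after their values were seen. Some genes that these rules take are not reported here.

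The fits were tested on simulated data of 12349 genes, with levels and noise taken from the real arrays and the noise shuffled over genes, of which 67 were changed 1.5-fold, 67 2-fold and 66 4-fold. The unpaired fit recovered 0 changed genes in each line at each size, and 17 of the 4-fold genes in the average. The fit to the 6 pair differences recovered 2 of the 1.5-fold, 20 of the 2-fold and 65 of the 4-fold genes in HCT116. In HL60 it recovered 1, 24 and 62 with 3 false calls, and in SNU398 0, 19 and 65. The fit to the pairs of 1 line, with 0 false calls, recovered 0, 0 and 62 in HCT116, 0 at each size in HL60, and 45, 63 and 66 in SNU398. The noise was drawn apart for each gene and array, so differences that many genes share between the arrays of a pair were absent. The false calls therefore do not measure the effect of such differences on the real calls. A list of 40 genes shifted by a log2 of 0.3 had a recovered median of 0.27 in HCT116, 0.32 in HL60 and 0.30 in SNU398. The number of arrays limits the precision of every value.

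Alternatives were array weights, a trend and robust variance, fits to the 4 arrays of a line, leaving out each array, other scalings, other gene filters, pair weights and leaving out the second pairs of HCT116 and HL60. Weights of the pairs, the scalings of the deposited values, gene filters on them and the second pairs left out were added after seeing the data.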

Results

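Gene expression was compared in 3 human cancer cell lines: HCT116, from a colon carcinoma, HL60, from a promyelocytic leukaemia, and SNU398, from a hepatocellular carcinoma. Cells of each line had received 5-Aza-CdR (decitabine), a cytosine analogue that traps DNA methyltransferases and thereby lowers DNA methylation, either alone or in a combination treatment whose other component the labels do not name. There were 2 arrays per group and 12 in all. Every difference reported here is the combination minus 5-Aza-CdR alone on the log2 scale, so the response to 5-Aza-CdR itself was not measured. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

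MPO set HL60 apart from SNU398, and KRT19 set HCT116 apart from both other lines, but other colon markers did not. MPO, the myeloperoxidase of granulocyte precursors, lay between log2 14.94 and 15.87 on the HL60 arrays and between 7.47 and 7.70 on the SNU398 arrays. KRT19, an epithelial keratin, lay between 11.24 and 13.14 on the HCT116 arrays against at most 7.76 elsewhere. EPCAM, an epithelial adhesion protein, did not part HCT116 from SNU398: it stood at 11.50 and 12.16 on the HCT116 replicate 1 arrays, at 8.16 and 8.57 on the replicate 2 arrays, and between 10.90 and 11.47 in SNU398. CDX2, also of the colon marker list, lay between 8.48 and 8.60 in HCT116, below its range of 9.16 to 9.54 in SNU398. Liver transcripts did not set SNU398 apart from HL60: ALB, the albumin gene of hepatocytes, lay between 8.17 and 8.27 in SNU398, below its range of 8.38 to 8.99 in HL60, and SERPINA1 between 7.67 and 7.76, below 10.84 to 11.56. Ribosomal protein transcripts, among the most abundant of a cell, had a median log2 of 14.22 and 14.38 on the HCT116 replicate 1 arrays (5-Aza-CdR and combination) but 11.59 and 11.99 on the replicate 2 arrays. In HL60 these medians were 15.03 and 15.03 against 12.96 and 13.78, and in SNU398 all 4 lay between 14.65 and 14.83. Rank correlations across genes between the 2 arrays of a group were 0.675 and 0.766 in HCT116, 0.703 and 0.846 in HL60, and 0.969 and 0.963 in SNU398. Arrays with the same replicate number were closer, between 0.875 and 0.985, and differences within such pairs were used beside the unpaired ones.

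**Figure D1:**
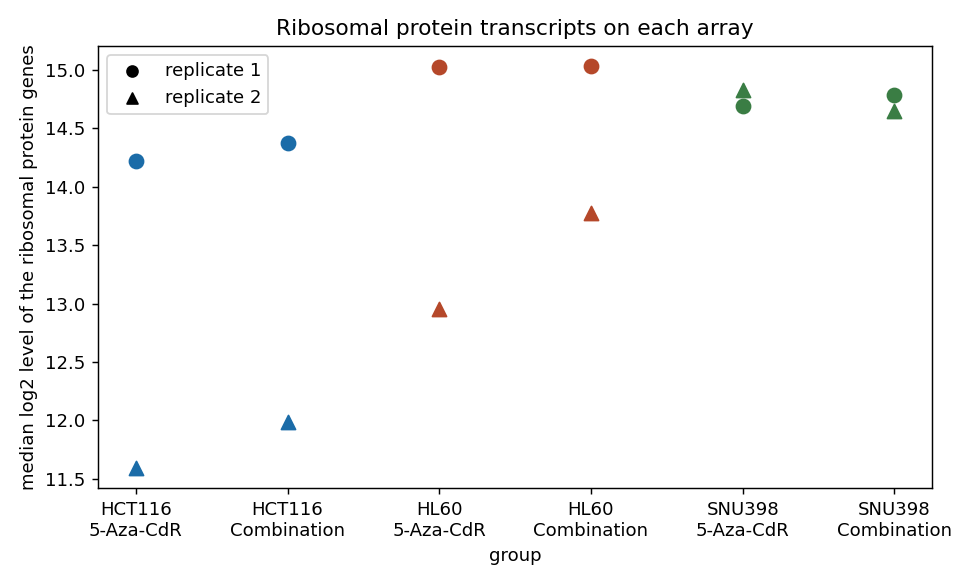
Median log2 level of the 46 ribosomal protein genes on each of the 12 arrays (vertical axis), by group (horizontal axis), with circles for replicate 1 and triangles for replicate 2. The replicate 2 arrays of HCT116 (11.59 and 11.99) and HL60 (12.96 and 13.78) sit below the replicate 1 arrays of the same line, and the SNU398 arrays lie together.

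In SNU398 cells a set of interferon-stimulated and germline transcripts was higher with the combination than with 5-Aza-CdR alone, and 9 of 43 mitotic and proliferation genes were lower. In the unpaired fit the interferon and mitotic lists as a whole had an adjusted p = 0.98 with an estimated correlation. REC8, a cohesin subunit of meiotic chromosomes, rose 2.68-fold (log2 1.42 ± 0.08 SE, n = 2 pairs), IFI27, an interferon-inducible mitochondrial protein, rose 2.44-fold (1.29 ± 0.09) and MX1, an interferon-induced antiviral GTPase, rose 2.29-fold (1.20 ± 0.09). APOE, the apolipoprotein of lipid transport, rose by 1.10, DPEP3 by 0.98, ARMCX2 by 0.90 and BTBD6 by 1.07. The germline genes ADAD2, RHOXF1, H2AFB1 and STRA8 rose by 1.08, 0.98, 0.85 and 0.84. TRIM48 fell by 1.64 and SPRYD5 by 1.33; both belong to a family of closely related tripartite-motif copies, which a probe may not tell apart. SFRP1, a secreted Wnt antagonist that is a known target of promoter methylation, fell by 1.01. HIST1H4C, NDFIP2, SCARNA9, EXOSC8, NRIP3, STX10 and GRIA2 fell by between 0.85 and 0.57. These changes passed limma in the fit to the pairs of SNU398, chosen after its calls had been seen, which called 710 of 19402 genes, 472 higher and 238 lower. Among the genes named, adjusted p ran from 6.8e-08 for TRIM48 to 0.0010 for STX10. The unpaired fit in limma called 0 genes (32 at an unadjusted p under 0.05) and the fit to all 6 pairs 0 (429). Both take 1 spread per gene from the 3 lines together. Weights that limma set by the spread of the pairs were 3.78 in SNU398, 0.62 in HCT116 and 0.43 in HL60. The fit to the pairs of SNU398 called 0 once pair 2 was turned round. That drop reflects the positive correlation of the 2 pairs, whatever its source. It does not tell the treatment from another difference common to both pairs. With a trend and robust variance 303 were called, 253 higher and 50 lower.

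**Figure D2:**
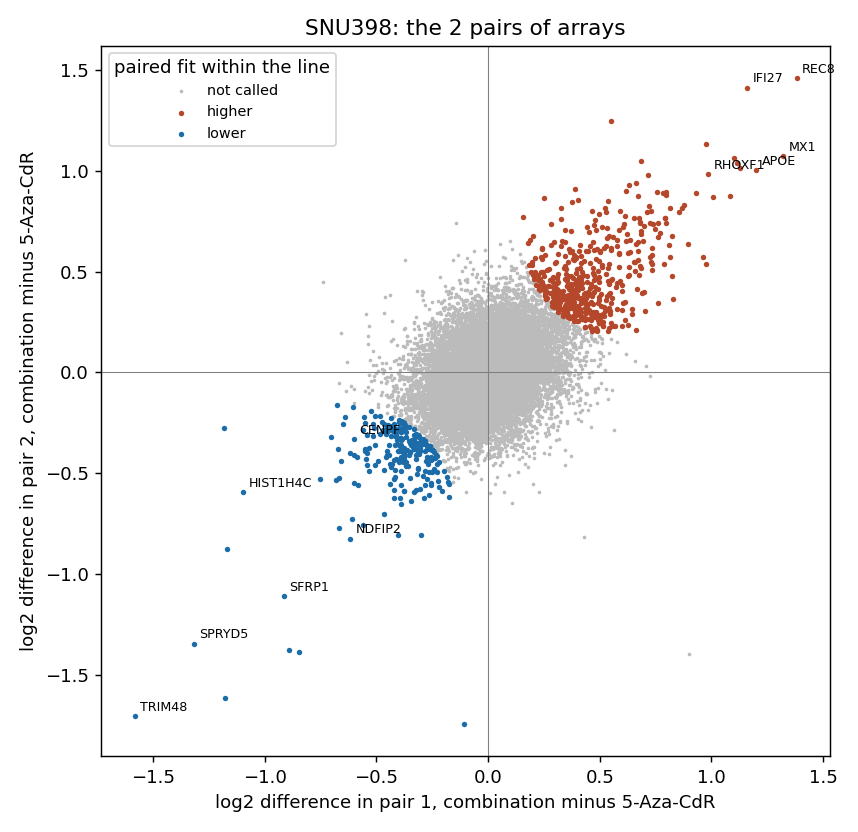
Log2 difference of each gene in SNU398, combination minus 5-Aza-CdR alone, in pair 1 (horizontal axis) and pair 2 (vertical axis), with the 472 higher and 238 lower genes of the fit to the pairs of this line in colour. The differences of the pairs correlated across genes by r = 0.444, and REC8 and TRIM48 stand at the ends.

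The interferon response genes of SNU398 had a median of 0.12, with 39 of 54 above 0. Of them 13 rose and 0 fell in the fit to the pairs of the line, and 15 rose adjusted over the list alone. Besides MX1 and IFI27 these included IFIT1, which binds viral RNA, by 1.06, PARP12 by 1.08, ISG15, a ubiquitin-like modifier, by 0.63, and the transcription factors STAT2 by 0.34 and IRF9 by 0.60. camera gave an adjusted p of 1.1e-08, but an adjusted p = 0.98 with an estimated correlation; on all 6 pair differences these were 2.9e-13 and 0.0056. The median was 0.08 without 5-Aza-CdR replicate 2.

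Cancer-testis and germline genes, which promoter methylation normally keeps silent in somatic cells, had a median of 0.11 in SNU398, with 50 of 64 above 0 (camera adjusted p = 1.1e-08; adjusted p = 0.036 with an estimated correlation, but 0.10 with an estimated correlation on the pair differences). In the fit to the pairs of the line 16 rose and 2 fell, and 22 rose and 3 fell adjusted over the list alone. CTCFL, the testis paralogue of the insulator protein CTCF, rose by 0.85, HORMAD1, a meiotic chromosome axis protein, by 0.80, TKTL1 by 0.78, TEX101 by 0.65, MAGEA8 by 0.52, LUZP4 by 0.40 and BRDT by 0.37, whereas TEX15 fell by 0.43 and FMR1NB by 0.41.

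Mitotic and proliferation genes had a median of -0.14 in SNU398, with 9 of 43 above 0 (camera adjusted p = 0.0011; adjusted p = 0.98 with an estimated correlation). Of these 9 fell and 0 rose, and 14 fell and 1 rose adjusted over the list alone. They were CENPF, a kinetochore protein (fell by 0.46), TYMS and RRM2, enzymes of nucleotide supply (fell by 0.43 and 0.38), the replicative helicase subunit MCM4 (fell by 0.39), CCNA2, CCNE2, KIF20A, DLGAP5 and HMMR. Without combination replicate 1 the median was -0.10 with an adjusted p of 0.21, without 5-Aza-CdR replicate 2 the adjusted p was 0.056, and without combination replicate 2 the median was -0.24.

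Replication-dependent histone genes had a median of 0.15 in SNU398 (camera adjusted p = 4.7e-04; adjusted p = 0.98 with an estimated correlation). Of 25, 6 rose and 1 fell, with 9 and 2 adjusted over the list alone. HIST1H1C, a linker histone gene, rose by 0.84, HIST2H2AA3 by 0.66 and HIST1H2AE by 0.33, and HIST1H4C was the one that fell. Without 5-Aza-CdR replicate 1 the adjusted p was 0.065. MHC class II genes had a median of 0.09 (9 genes, camera adjusted p = 0.035; adjusted p = 0.98 with an estimated correlation, 0.0056 on the pair differences), with HLA-DMA, a peptide-loading chaperone subunit, the 1 gene called (0.71), and 2 rose adjusted over the list alone. Leaving out 5-Aza-CdR replicate 1, combination replicate 1 or 5-Aza-CdR replicate 2 of SNU398 ended that list's call, with adjusted p of 0.068, 0.75 and 0.31 and medians of 0.13, 0.04 and 0.09. NRF2 antioxidant genes were called on the pair differences only (median 0.10, camera adjusted p = 8.4e-04; adjusted p = 6.0e-04 with an estimated correlation; 0.23 unpaired), with HMOX1, NQO1, FTH1 and FTL, genes of haem, quinone and iron handling, called higher by 0.58, 0.64, 0.42 and 0.33, and 8 of 29 rose adjusted over the list alone.

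In HCT116 cells a set of interferon-stimulated genes was higher with the combination than with 5-Aza-CdR alone, 11 of the 43 of the interferon response list in a fit to the pairs of the line that was chosen after its calls had been seen. In the unpaired fit the list as a whole had an adjusted p = 0.11 with an estimated correlation. IFITM3, which restricts virus entry at endosomal membranes, rose 3.20-fold (log2 1.68 ± 0.22 SE, n = 2 pairs), MX1 rose 2.72-fold (1.44 ± 0.22), IFITM2 by 1.06 and OASL, an oligoadenylate synthetase-like protein, by 1.09. The 2 pairs stood at 1.60 and 1.75 for IFITM3 and at 1.44 and 1.45 for MX1, so both SEs come mainly from the spread moderated over genes. TAPBP, the tapasin chaperone that loads peptide on MHC class I, rose 2.03-fold, and FAM46A and C1ORF71 both rose by 1.00. D2HGDH, which oxidises D-2-hydroxyglutarate, fell by 1.06, the kinetochore gene SPC24 by 1.01 and RNU11, a small RNA of the minor spliceosome, by 0.95. limma called 25 of 12349 genes in the fit to the pairs of HCT116, 21 higher and 4 lower. The adjusted p was 1.6e-05 for IFITM3, 2.8e-04 for MX1, 0.016 for IFITM2, 0.011 for OASL, 0.027 for TAPBP, 0.044 for FAM46A and 0.046 for C1ORF71, D2HGDH, SPC24 and RNU11. The unpaired fit in limma called 0 (4 at an unadjusted p under 0.05) and the fit to all 6 pairs called 0 (1011, smallest adjusted p 0.063). Turning pair 2 round left 2 calls, which again does not tell the treatment from another difference common to both pairs. The 25 calls became 0 after quantile normalization or with a trend and robust variance, 18 after centring the arrays, and 2 among genes with a mean log2 of at least 9.

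The interferon response list of HCT116 had a median of 0.51 with 40 of 43 genes above 0 (camera adjusted p = 8.2e-30; adjusted p = 0.11 with an estimated correlation; 1.0e-21 and 7.4e-05 on the pair differences). In the fit to the pairs 11 rose and 0 fell, and 21 rose adjusted over the list alone. Besides those named they included OAS1 at 1.36, LGALS3BP at 1.28, SAMD9 at 1.24, the RNA helicase sensor IFIH1 at 1.10, IFI6 at 1.10 and IFI27 at 0.99. Leaving out 1 array sets arrays of unequal signal against each other. The median was 1.10 without 5-Aza-CdR replicate 1, 0.10 without combination replicate 1, -0.01 without 5-Aza-CdR replicate 2 and 0.99 without combination replicate 2. In pair 1 alone it was 0.24 over the 52 genes measured there, and 0.32 over the same 43 genes.

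Of the other lists in HCT116, camera called NRF2 antioxidant genes (median 0.22, adjusted p = 0.021; 2.4e-04 with an estimated correlation on the pair differences), metallothioneins and zinc transport (0.42, adjusted p = 0.0018), MHC class I antigen presentation (0.19, adjusted p = 0.0086), NF-kappaB and inflammatory cytokines (0.08, adjusted p = 0.021), double-stranded RNA and DNA sensing (0.08, adjusted p = 0.036; 0.11 on the pair differences), colon epithelial markers (0.26, adjusted p = 0.042) and, downwards, collagens and collagen-modifying enzymes (-0.05, adjusted p = 0.042). Each of these 7 lists had an adjusted p = 0.97 with an estimated correlation. In the fit to the pairs 1 gene rose in each of the MHC class I, NF-kappaB and sensing lists, and 0 in the other 4. Adjusted over the list alone these were 1, 2 and 2, with 4 metallothionein or zinc genes and 0 in the remaining 3. Among their genes NFKB1, a subunit of NF-kappaB, rose by 1.00 (adjusted p = 0.032), beside TAPBP and IFIH1. The values of NFKBIA, its inhibitor, were 0.81, of MT2A, a metal-binding metallothionein, 0.79, of the zinc-sensing factor MTF1 0.77, of IRF7 0.88 and of KRT19 0.60, none of which was called in limma. The ribosomal protein medians of the HCT116 pairs were 0.05 and 0.32, and those of MHC class I were -0.00 and 0.53. Each of the 4 HCT116 arrays, left out in turn, ended the call, turned the direction or moved the median by over 1.5 times for all 7 lists. The NRF2 median ran from -0.69 (without combination replicate 1) to 1.26 (without combination replicate 2), and that of collagens from -0.33 (without combination replicate 1) to 0.23 (without 5-Aza-CdR replicate 1). Without 5-Aza-CdR replicate 2 and 5-Aza-CdR replicate 1 the medians were -0.54 and 0.84 for MHC class I, -0.43 and 0.79 for NF-kappaB, and -0.54 and 1.43 for metallothioneins. They were -0.44 and 0.71 for nucleic acid sensing and -0.50 and 1.11 for colon markers in the same order. Leaving out either HL60 5-Aza-CdR array also ended the collagen and colon marker calls of HCT116 (adjusted p = 0.064). In pair 1 alone the NF-kappaB median was -0.10, and the sensing, MHC class I, collagen, NF-kappaB and colon calls ended (adjusted p = 0.39, 0.84, 0.32, 0.39 and 0.84).

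**Figure D3:**
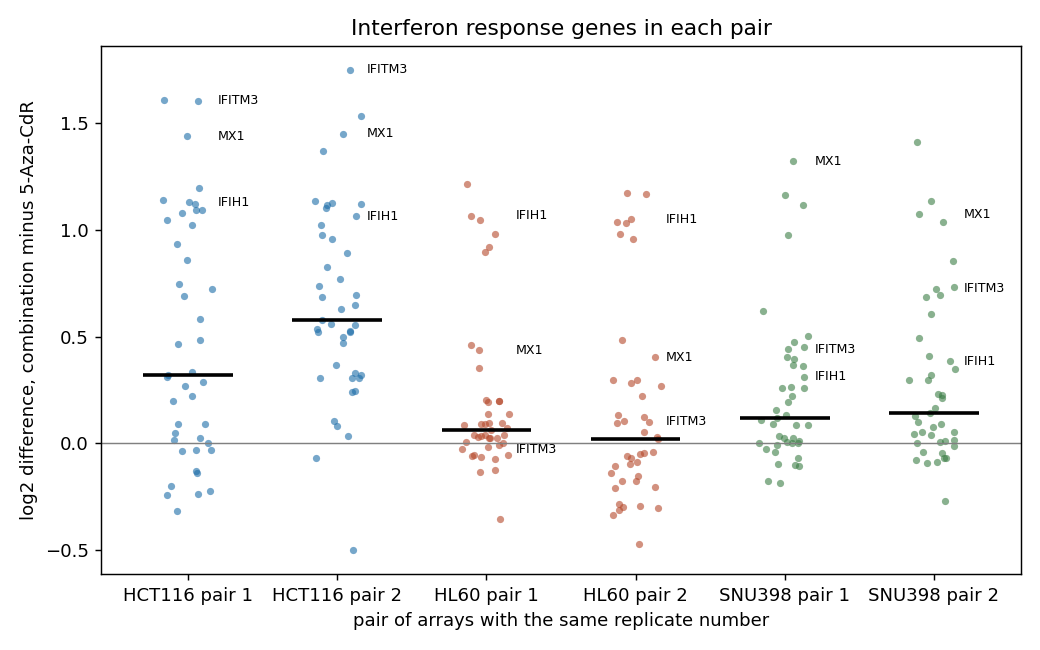
Log2 difference, combination minus 5-Aza-CdR alone (vertical axis), of the 43 interferon response genes measured in every pair, for each of the 6 pairs of arrays (horizontal axis), with black lines at the medians. The medians were 0.32 and 0.58 in HCT116, 0.06 and 0.02 in HL60, and 0.12 and 0.14 in SNU398, and in HL60 a few genes such as IFIH1 lie apart near a difference of 1.

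In HL60 cells a small set of immune genes was higher with the combination in both pairs, while the median of the interferon response list lay near 0 (0.03). IFIT2 (1.19), IFI16 (1.19), IFIH1 (1.06) and ISG20 (1.04), antiviral effectors and nucleic acid sensors, the MHC class I genes B2M (1.21) and HLA-B (1.07) and the monocyte chemokine CCL2 (1.73) were the 7 genes at least 2-fold higher in both pairs, chosen after their values were seen. Independent pairs would give 0.64 such genes, from 12 that were 2-fold higher in pair 1 and 1027 in pair 2. That figure gives every gene the same chance of a 2-fold difference. Genes that vary more can recur in both pairs without an effect of the treatment, so the excess does not measure one. No gene was 2-fold lower in pair 1, so the pairs could not be compared in that direction. None was called: limma gave 0 genes of 19402 in the unpaired fit (26 at an unadjusted p under 0.05), in the fit to all 6 pairs (1417, adjusted p = 0.39 for these 7) and in the fit to the pairs of HL60 (184, adjusted p = 0.895). The genes with the smallest p were PPP1R2P9 (1.54 ± 0.38 SE, n = 2 arrays per group), CD3D (0.89 ± 0.27), ACP5, the phosphatase of osteoclasts and macrophages (0.91 ± 0.26), the RNA sensor DHX58 (0.98 ± 0.33) and C20ORF118 (1.00 ± 0.31). The pairs of HL60 differed in spread, with SDs over genes of 0.158 and 0.552, and correlated by r = 0.083.

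The interferon response list had a median of 0.03 in HL60 and a mean of 0.15, with 31 of 54 genes above 0 (camera adjusted p = 0.22). Its median was -0.04 with the arrays centred and -0.01 after quantile normalization, and 0.04 in pair 1 alone. Adjusted over the list alone, 7 genes rose in the fit to the pairs of HL60, against 0 over all genes. NF-kappaB and inflammatory cytokine genes had a median of 0.31 with 22 of 27 above 0 (camera adjusted p = 0.0016; adjusted p = 0.98 with an estimated correlation), with values of 1.08 for IL1B, 0.95 for RELB, 0.93 for the chemokine CCL20, 0.93 for IER3 and 0.59 for TNFAIP2. Adjusted over the list alone, 8 of these rose on all 6 pair differences and 0 in the fit to the pairs of HL60. The fit to all 6 pairs takes its spread partly from the SNU398 pairs (weight 3.78 against 0.43 in HL60), so its p for HL60 may be too small. In limma it put 7.30% of HL60 genes at an unadjusted p under 0.05, against 0.95% in the fit to the pairs of HL60. Double-stranded RNA and DNA sensing genes had a median of 0.13 (24 genes, camera adjusted p = 0.0058; adjusted p = 0.98 with an estimated correlation, 0.020 on the pair differences) and pair medians of 0.036 and 0.25, including AIM2, a DNA sensor, at 0.85 and C6ORF150, the cyclic GMP-AMP synthase, at 0.46. Ribosomal protein genes had a median of 0.39 with 42 of 46 above 0 (camera adjusted p = 0.0058; adjusted p = 0.98 with an estimated correlation), with RPL23 at 0.48, RPS19 at 0.38 and RPL4 at 0.32, but the medians of the pairs were 0.04 and 0.69. The gap between the array medians of pair 2 (12.96 with 5-Aza-CdR and 13.78 with the combination) comes from the same genes and is no separate sign of array quality. In pair 1 alone the adjusted p of this list was 0.085. Each of the 4 HL60 arrays, left out in turn, ended or moved these 3 calls: the ribosomal protein median was 1.00 without 5-Aza-CdR replicate 1, 0.06 without combination replicate 1, -0.23 without 5-Aza-CdR replicate 2 and 0.67 without combination replicate 2, the NF-kappaB median 0.61, 0.13, 0.0022 and 0.56 in the same order, and the sensing median 0.30, 0.24, 0.09 and 0.27.

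On the pair differences alone, further lists were called in HL60: myeloid and granulocyte markers (median 0.20; camera adjusted p = 0.016; adjusted p = 0.012 with an estimated correlation), NRF2 antioxidant genes (0.25; 0.013; 0.012 with an estimated correlation) and MHC class II genes (0.23; 0.027; 0.042 with an estimated correlation). The medians of pairs 1 and 2 were 0.033 and 0.35 for the myeloid list, 0.18 and 0.23 for NRF2 genes, and 0.21 and 0.17 for MHC class II genes. The myeloid markers that lay highest were NCF1, a subunit of the phagocyte oxidase (1.03), the signalling adaptors FCER1G (0.76) and TYROBP (0.72) and the lipopolysaccharide receptor CD14 (0.68), whereas the granule proteases ELANE and CTSG stood at -0.43 and -0.33. CD74, the invariant chain of MHC class II, stood at 0.73. MHC class I genes (0.19; adjusted p = 0.0051), immediate early genes (0.10; adjusted p = 0.013) and oxidative phosphorylation genes (0.27; adjusted p = 7.8e-04) were also called on the pair differences, with adjusted p of 0.40, 0.21 and 0.78 with an estimated correlation. Their pair medians were 0.12 and 0.31, 0.12 and 0.10, and -0.0097 and 0.53, so the oxidative phosphorylation and myeloid medians came mostly from pair 2.

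On average over the 3 lines MX1 rose by 1.02 (2.02-fold), higher in 6 of 6 pairs, and it was the 1 gene of 12349 called by limma on the 6 pair differences (adjusted p = 0.032), against 0 in the unpaired fit. IFIH1 (0.83, adjusted p = 0.052), IFIT1 (0.69, adjusted p = 0.14) and the interferon regulatory factor IRF7 (0.64, adjusted p = 0.17) were higher in 6 of 6 pairs but not called. In the unpaired fit the 5 smallest p belonged to MX1, IRF7, DPEP3 (0.61), RHOXF1 (0.68) and H2AFB1 (0.52), the last 3 with an adjusted p of 0.438, 0.422 and 0.313 on the pair differences. The germline RNA-binding gene DAZL stood at 0.66 and NQO1 at 0.54, above 0 in 6 of 6 pairs, and CENPF at -0.37, below 0 in all 6. CENPF does not stand for its mitotic list, whose medians were 0.065 and 0.12 in the HCT116 pairs. In HL60 they were -0.057 and 0.31, and in SNU398 -0.18 and -0.11. At an unadjusted p under 0.05 the unpaired limma fit had 5 genes and the paired fit 1041.

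Over the lines the interferon response list had a median of 0.31 with 39 of 43 above 0 (camera adjusted p = 3.7e-24; adjusted p = 0.27 with an estimated correlation; 5.6e-19 and 1.6e-04 on the pair differences) and a list median above 0 in 6 of 6 pairs. In HL60 pair 2 that median, 0.017 over 54 genes, lay under the median of all genes of the pair (0.046) and at percentile 29.5 of random lists, so the list was not raised against other genes there. On the pair differences 1 rose over all genes and 22 rose adjusted over the list alone. Without HCT116 5-Aza-CdR replicate 1, combination replicate 1 or 5-Aza-CdR replicate 2 the median was 0.48, 0.11 and 0.09, and with the second pairs of HCT116 and HL60 left out it was 0.18. The NRF2 antioxidant list, also above 0 in 6 of 6 pairs, had a median of 0.19 (camera adjusted p = 0.0028; adjusted p = 0.97 with an estimated correlation, 1.0e-05 on the pair differences), with AKR1C3 at 0.45, HMOX1 at 0.42 and MAFG at 0.31, and 6 of 27 rose adjusted over the list alone on the pair differences. Without HCT116 5-Aza-CdR replicate 1, combination replicate 1, 5-Aza-CdR replicate 2 and combination replicate 2 its median was 0.55, -0.12 (adjusted p = 0.31), -0.13 (adjusted p = 0.13) and 0.56. Without the HL60 arrays in the same order it was 0.31, 0.09 (adjusted p = 0.42), 0.09 (adjusted p = 0.12) and 0.33.

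fry tests whether the genes of a list move on balance in 1 direction, here over the genes measured on all 12 arrays. In the unpaired fit it called none of the lists in any line or in the average, with adjusted p of at least 0.984. On the pair differences it called NRF2 antioxidant, interferon response and, downwards, collagen genes in HCT116 (adjusted p = 0.013, 0.026 and 0.044), and NRF2 antioxidant, interferon response and sensing genes on average over the lines (adjusted p = 0.024, 0.025 and 0.049). It called none in HL60, where NRF2 genes had an adjusted p of 0.056 and myeloid markers 0.25, and none in SNU398, where NRF2 genes had 0.078, interferon response genes 0.16, cancer-testis genes 0.59 and mitotic genes 0.80. The other list calls named above rest on camera alone.

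**Figure D4:**
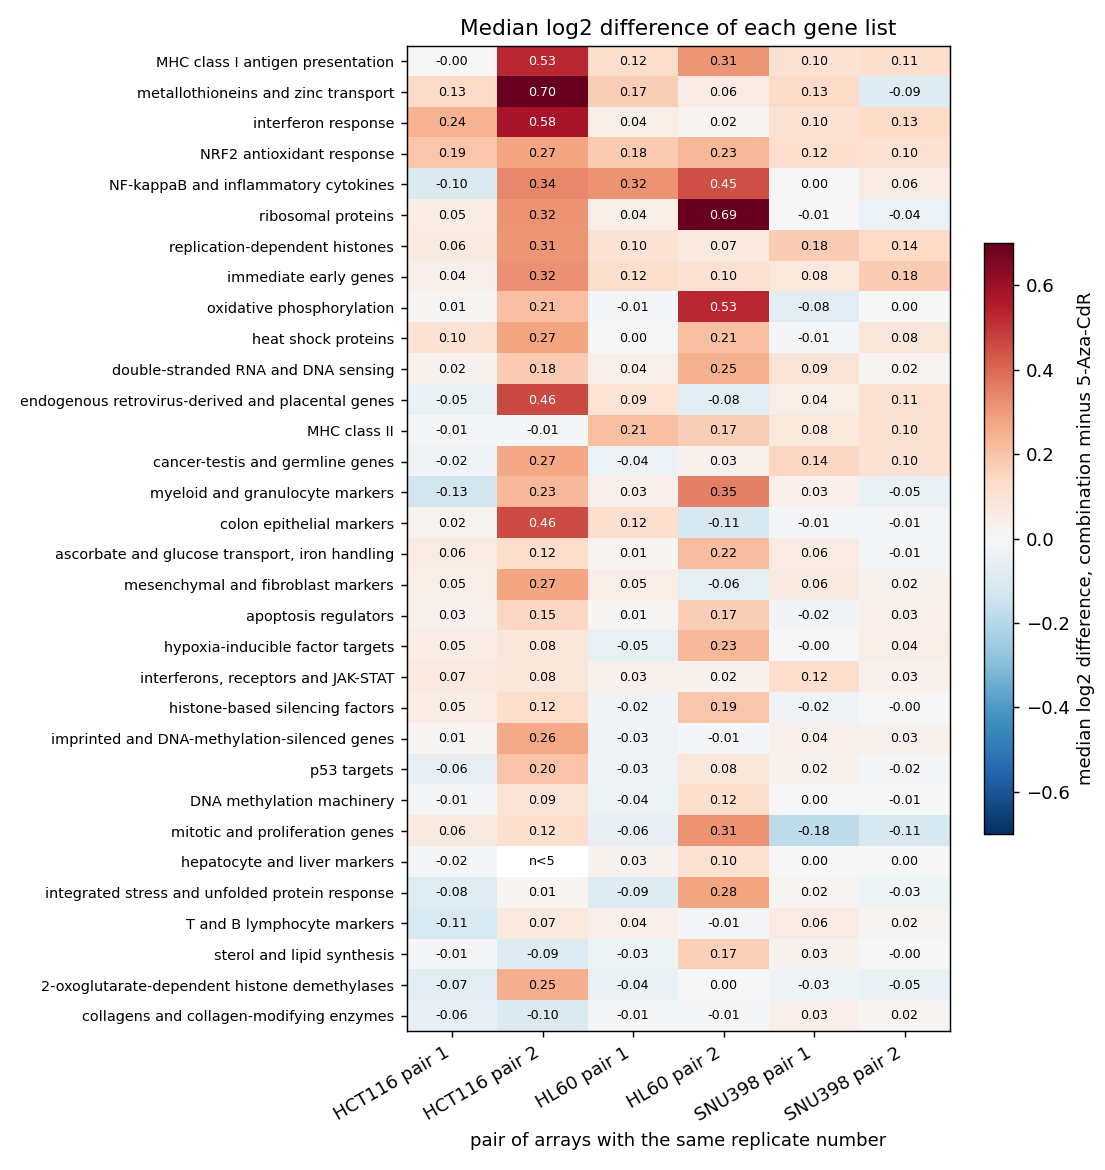
Median log2 difference, combination minus 5-Aza-CdR alone, of each of the 32 gene lists (vertical axis) in each of the 6 pairs of arrays (horizontal axis), over the members measured in that pair, with colour from blue (lower) to red (higher). The interferon response list stands at 0.24 and 0.58 in HCT116, 0.04 and 0.02 in HL60, and 0.10 and 0.13 in SNU398, and its value in HL60 pair 2 lies under the median of all genes of that pair, 0.046.

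Between HCT116 and SNU398 the genes called in the fits to the pairs of each line overlapped: 7 genes were higher in both, of 21 and 375 among 12349, where independent lists would share 0.64, and 1 was lower in both, of 4 and 182, where independent lists would share 0.059. These figures give every gene the same chance of a call. The 7 included IFITM3, MX1, BLOC1S1, IFIH1, IFITM2 and IFI27, and the 1 lower in both was SPC24. Across all genes the differences of these lines correlated by r = -0.040, those of HL60 and SNU398 by 0.050 and those of HCT116 and HL60 by 0.445, where genes are not independent replicates. This last value was 0.0063 between the first pairs of the lines and 0.469 between the second pairs.

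Whether the response differed between lines was tested for each gene. limma called 0 of 12349 genes in the moderated F test (0 at an unadjusted p under 0.05), and 0 on the pair differences (399). Were no gene different, a share near 0.05 would lie under that limit, and on the pair differences 3.23% did. In the unpaired contrasts within HCT116, HL60 and SNU398 the share was 0.032%, 0.13% and 0.16%. The unpaired tests were too strict here, since their spread holds the replicate deviations shared within pairs. The absence of calls therefore does not show that no gene differed between lines. The smallest p belonged to REC8, which stood at 1.42 in SNU398 against 0.09 in HCT116 and -0.01 in HL60, and to SPRYD5, at -1.33 in SNU398 against 0.03 and 0.16. FAM46A and TAPBP stood at 1.00 and 1.02 in HCT116, 0.01 and -0.18 in HL60, and -0.29 and 0.09 in SNU398. ADAD2 had its largest value in SNU398 (1.08), GAGE6 and PPARG, a lipid-sensing nuclear receptor, in HL60 (0.63 and 0.92), IFITM3 in HCT116 (1.68), and NES and LTBP4 stood at -0.62 and -0.61 in HCT116 and 0.38 and 0.30 in SNU398. Each had an adjusted p of 1.00 in the unpaired fit and 0.86 on the pair differences.

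DNMT1, the maintenance methyltransferase that 5-Aza-CdR traps, stood at -0.00 in HCT116, 0.29 in HL60 and -0.04 in SNU398, and TET1, which oxidises methylcytosine, at -0.14, 0.37 and -0.24; TET3 stood at -0.02 in HL60 and -0.05 in SNU398. None was called in limma, with adjusted p of at least 0.15 in the fits to the pairs of each line.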

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

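The tests on splits of the arrays, quantile scaling, the first pairs of the lines and lists matched on signal were chosen after the result was seen; the 2 tests that regress the replicate difference out of the pairs were set before.

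The results in this part stood out because a gene list moved by different amounts in 2 lines, by a camera test of the difference itself. The interferon response list, which holds antiviral effectors and their regulators, was 0.285 lower on the log2 scale in HL60 than in HCT116 (difference of the combination effects -0.285, 43 genes, adjusted p = 1.1e-12; adjusted p = 0.94 with an estimated correlation; 3.0e-12 and 0.013 on the pair differences). Between SNU398 and HCT116 the difference of that list was -0.247 (43 genes, adjusted p = 5.8e-07; adjusted p = 0.99 with an estimated correlation, 0.19 on the pair differences). Mitotic and proliferation genes differed by -0.231 between SNU398 and HCT116 (38 genes, adjusted p = 0.011; 0.99 with an estimated correlation) and by -0.201 between SNU398 and HL60 (43 genes, adjusted p = 0.024; 0.97 with an estimated correlation). Cancer-testis and germline genes differed by 0.145 between SNU398 and HL60 (64 genes, adjusted p = 0.0029; 0.97 with an estimated correlation). Between SNU398 and HL60, NF-kappaB and inflammatory cytokine genes differed by -0.382 (27 genes) and ribosomal protein genes by -0.424 (46 genes), both with an adjusted p of 0.014 and of 0.97 with an estimated correlation. Between SNU398 and HCT116, metallothioneins and zinc transport genes differed by -0.375 (10 genes) and collagens and collagen-modifying enzymes by 0.142 (22 genes), both with an adjusted p of 0.011 and of 0.99 with an estimated correlation. Of these 7 differences outside the interferon list, that of collagens alone stayed under the threshold with an estimated correlation on the pair differences (adjusted p = 0.022).

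The interferon response list was higher with the combination on average over the lines, with a median of 0.31; with the pairs kept, 1 of the 32 ways to turn pairs round gave a median as far from 0, the real one and the smallest share that 32 ways can give, and the highest of the others was 0.26. For this list taken alone, which was named in advance as that of most interest, that share is under 0.05. This does not hold over all 32 lists, of which 6 had medians above 0 in 6 of 6 pairs. The test was chosen after the result was seen and takes the pairs as independent. The second pairs of HCT116 and HL60 correlated across genes by r = 0.469, so turning pairs round cannot exclude chance. Without regard to pairs, 24 of 100 splits of the arrays within lines gave a median as large (highest other 0.52), so chance cannot be excluded there. Of these 24, 23 separate the replicate numbers in at least 1 line, against 71 of all 100 splits. Regressing the difference between replicates and the signal level out of each pair left the median at 0.310, against -0.0998 to 0.0881 in random lists matched on signal, although that of HL60 pair 2 turned from 0.022 to -0.025, and quantile scaling within lines left 0.291, which argues against array quality of that form and against scaling as the whole cause. A response of interferon genes to the combination stays open as a hypothesis, beside differences between the cultures or arrays of a pair that these 12 arrays do not resolve.

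The difference between the treatments in the second pair of HCT116 resembled that in the second pair of HL60, with r = 0.469 across genes, which are not independent replicates. The first pairs of these lines correlated by 0.0063 (bootstrap interval -0.013 to 0.027, with genes taken as independent). This argues against a response of like size in both pairs, shared by both lines, as the whole cause. A weaker shared response is not excluded, because the 2 pairs of 1 line correlated by only 0.179 in HCT116 and 0.083 in HL60. The difference between replicates 1 and 2 was itself alike in HCT116 and HL60 (r = 0.701) but not in HCT116 and SNU398 (r = -0.138), and with the signal level it took up 25.5% and 45.2% of the variance of these second pairs. Regressing it out lowered the correlation to 0.268 (0.252 to 0.285), between the limits set for and against array or RNA quality, so the part that quality may hold cannot be told from these values.

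In SNU398 the median of mitotic genes was -0.143, outside the range of 10000 random lists matched on signal (-0.122 to 0.106), and that of cancer-testis genes was 0.111, also outside theirs (-0.0766 to 0.0595). A shift between arrays that depends on signal level is therefore an unlikely source of either. Both medians had the same sign in both pairs, but the mitotic list had an adjusted p = 0.98 with an estimated correlation. Slower growth of the SNU398 cells in the combination cultures, a difference in density between cultures, and a response of germline promoters remain open and were not tested.

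On average over the lines the unpaired limma fit called 0 genes (5 at an unadjusted p under 0.05). No split of the arrays within lines can give fewer than 0, so the 100 of 100 splits with at least as many say nothing about chance. The highest other split called 8630 genes, which points to a structure of the samples apart from the treatments. Of the 100 splits, 71 separate the replicate numbers in at least 1 line. The way of splitting sets that share whatever the data, so it does not show what the structure is. On the 6 pair differences 1 gene, MX1, was called.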

How the results depend on the processing

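Except for the block of the replicate number, fits to the 4 arrays of a line, array weights, a trend with robust variance, leaving out arrays, estimated correlations in the unpaired fit, list means and a 2-fold minimum, these tests were chosen after the result was seen. Each line holds 2 arrays per group, and where 1 was left out the lone array was assumed to vary like the other groups. Ribosomal protein medians were lower on the second arrays of HCT116 and HL60. Background was not measured, and detection p-values were not used here. An offset, no background correction, scaling after background correction, detection filters, tests per probe and a block for the chip were not run, because no column of the bead table matches a sample.

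The unpaired counts were 0 in every line, in the average and between lines, also under every array left out, array weights, a trend with robust variance, both scalings, both gene filters and the second pairs left out. In HCT116 the pairs of the line alone gave 25 calls, pair weights 1, centred arrays within the pairs 18, a mean log2 of at least 9 within the pairs 2, and a 2-fold minimum 19. In SNU398 the same settings gave 710, 408, 674, 482 and 15, quantile scaling within the pairs 686, and a trend with robust variance within the pairs 303. Of the 710 genes, 674, 684 and 303 were also called with the same sign after centring, quantile scaling and the trend, as were all 410 of those tested with a mean log2 of at least 9. On average over the lines the replicate block called 1 gene and pair weights 5. The cause of these differences was not tested. Beyond the calls named with the results, the block changed no other call of a count.

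With an estimated correlation the interferon list lost its call in HCT116 (0.51, adjusted p = 0.11), SNU398 (0.12, adjusted p = 0.98) and the average (0.31, adjusted p = 0.27). In HL60 its median was -0.042 on centred arrays and -0.015 after quantile scaling, with or without the pairs, and it was called (0.039) once the second pairs were left out. That setting also gave -6.8e-05 for MHC class I and -0.10 for NF-kappaB in HCT116.

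With 1 array left out, medians in HCT116 ran from -0.0092 to 1.10 for interferon response, -0.44 to 0.71 for nucleic acid sensing, -0.54 to 0.84 for MHC class I, -0.33 to 0.23 for collagens, -0.69 to 1.26 for NRF2, -0.43 to 0.79 for NF-kappaB, -0.54 to 1.43 for metallothioneins and -0.50 to 1.11 for colon markers. In HL60 they ran from -0.039 to 0.14 for interferon response and -0.23 to 1.00 for ribosomal proteins. In the average they ran from -0.080 to 0.31 for sensing, -0.037 to 0.27 for JAK-STAT, -0.013 to 0.35 for MHC class I, -0.090 to 0.32 for MHC class II, -0.13 to 0.56 for NRF2, -0.18 to 0.55 for metallothioneins, -0.14 to 0.58 for immediate early genes and -0.18 to 0.64 for ribosomal proteins. The lowest value fell without HCT116 5-Aza-CdR replicate 2 (collagens, JAK-STAT, MHC class II and NRF2 in HCT116: without combination replicate 1), and in HL60 without 5-Aza-CdR replicate 1 (interferon) or 2 (ribosomal proteins). By construction such a difference holds the gap between replicates. Of the other values, 4867 of named genes stayed, 179 moved and 208 passed the threshold. Of other lists 2715 stayed, 267 moved, 33 reversed, 133 passed it and 169 lost it. Here a value stayed if its sign and its side of the threshold were the same. Leaving out an array of another line cannot change a log2 value within a line, and the unpaired fit called no gene. Much of these totals was thus fixed in advance, and they do not measure stability.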

Other observations

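The lists and their camera tests in this part were set before the result was seen, except for estimated correlations on the pair differences, which were added later. The fit to the pairs of 1 line was chosen after its calls had been seen.

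In SNU398 further groups held genes called by limma in the fit to the pairs of the line. Of the interferon receptor and JAK-STAT genes 5 rose and 0 fell (6 and 1 adjusted over the list alone), among them the receptor chain IL10RB (0.34) and the kinase TYK2 (0.34), beside STAT2 and IRF9, which the interferon response list also holds. The list median was 0.04 (camera adjusted p = 0.59 unpaired, 0.018 on the pair differences; adjusted p = 0.31 with an estimated correlation). Immediate early genes, which answer growth factor signals, had a median of 0.17 (0.093 unpaired, 8.4e-04 on the pair differences; adjusted p = 0.069 with an estimated correlation). CTGF, SGK1, ZFP36 and NR4A2 rose by 0.43, 0.40, 0.36 and 0.33, and DUSP6, a phosphatase of ERK, fell by 0.36, the same 4 and 1 genes in number as adjusted over the list alone. TAP1, the peptide transporter, rose by 0.50, the 1 MHC class I gene called (1 adjusted over the list alone; list median 0.10, adjusted p = 0.014 on the pair differences; adjusted p = 0.47 with an estimated correlation). Of the sensing genes 3 rose (5 adjusted over the list alone), TRIM25 by 0.32, with a median of 0.03 (0.035 on the pair differences, 0.038 with an estimated correlation). Collagen genes had a median of 0.02 (adjusted p = 0.0498 unpaired, 0.054 on the pair differences; adjusted p = 0.98 with an estimated correlation), with COL9A2 and PLOD1 up by 0.71 and 0.38 and 4 up adjusted over the list alone. That call ended without SNU398 5-Aza-CdR replicate 1 (median 0.070, adjusted p = 0.068), combination replicate 1 (0.028, adjusted p = 0.88) or 5-Aza-CdR replicate 2 (3.8e-04, adjusted p = 0.59), and the median was 0.072 without combination replicate 2. It also ended when any 1 of the HCT116 arrays was left out (adjusted p between 0.059 and 0.076).

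Among silenced or imprinted genes of SNU398, GSTP1, a detoxifying enzyme, rose by 0.69, CYGB by 0.62 and the imprinted RNA MEG3 by 0.39, and SFRP1 fell (4 and 1 adjusted over the list alone; list median 0.02, adjusted p = 0.74). Of iron and ascorbate genes 4 rose, GSTO2 by 0.35 beside FTH1, FTL and HMOX1 of the NRF2 list, and the transferrin receptor TFRC fell by 0.36 (4 and 1 adjusted over the list alone; median -0.01 but mean 0.05, test upwards, adjusted p = 0.74). Hypoxia genes ALDOC and DDIT4 rose by 0.48 and 0.43 (5 adjusted over the list alone; median -0.00, mean 0.04, adjusted p = 0.50). The silencing factors AOF2, the histone demethylase LSD1, and CBX1, a heterochromatin protein, fell by 0.47 and 0.31 (3 adjusted over the list alone; adjusted p = 0.70). HSPB1 rose by 0.34 and HSPE1 fell by 0.34 among heat shock genes, whose median (0.04) and mean (0.01) lay above 0 with the test downwards (adjusted p = 0.79; 1 and 2 adjusted over the list alone). ASGR1, a liver lectin, rose by 0.48, and RPL22 and COX7A2 both fell by 0.32.

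On average over the lines camera also called MHC class I genes, with 15 of 15 above 0 (median 0.21, adjusted p = 6.4e-05), NF-kappaB genes (0.20, 1.5e-05), sensing genes (0.08, 0.0029), cancer-testis genes (0.09, 0.0034), ribosomal proteins (0.18, 0.0080) and MHC class II genes (0.10, 0.017). It called immediate early genes (0.16, 0.030), metallothioneins (0.22, 0.0495) and JAK-STAT genes (0.12, 0.0495) as well. With an estimated correlation none was called, with adjusted p = 0.44 for MHC class I, NF-kappaB and cancer-testis genes, 0.89 for sensing, 0.85 for MHC class II, 0.95 for JAK-STAT and 0.97 for the others; on the pair differences sensing had 0.041. Without HCT116 5-Aza-CdR replicate 2 the medians of MHC class I, sensing, metallothionein, immediate early, ribosomal and MHC class II genes were -0.013, -0.080, -0.18, -0.14, -0.18 and -0.054, and those of NF-kappaB, cancer-testis and JAK-STAT genes 0.032, 0.0079 and 0.0011. Without HCT116 combination replicate 1 those of JAK-STAT, MHC class II, sensing, metallothionein, immediate early and ribosomal genes were -0.037, -0.090, -0.044, -0.12, -0.13 and -0.17, and that of MHC class I genes 0.037. Without HCT116 5-Aza-CdR replicate 1 the medians of MHC class I, NF-kappaB, sensing, cancer-testis and MHC class II genes were 0.35, 0.41, 0.31, 0.20 and 0.32, and those of JAK-STAT, metallothionein, immediate early and ribosomal genes 0.27, 0.55, 0.58 and 0.64. Without HCT116 combination replicate 2 those of NF-kappaB, sensing, cancer-testis and MHC class II genes were 0.35, 0.28, 0.15 and 0.30, and those of JAK-STAT, metallothionein, immediate early and ribosomal genes 0.27, 0.49, 0.50 and 0.55.

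The HL60 arrays moved these medians of the average as well. JAK-STAT, metallothionein and ribosomal genes stood at 0.27, 0.37 and 0.41 without 5-Aza-CdR replicate 1, at 0.014, -0.021 and 0.073 without combination replicate 1, at 0.018, 0.049 and -0.047 without 5-Aza-CdR replicate 2, and at 0.21, 0.38 and 0.30 without combination replicate 2. Sensing genes stood at 0.16 without 5-Aza-CdR replicate 1, 0.036 without 5-Aza-CdR replicate 2 and 0.13 without combination replicate 2. NF-kappaB and MHC class II genes stood at 0.12 and 0.16 without combination replicate 1 and at 0.11 and 0.19 without 5-Aza-CdR replicate 2, and immediate early genes at 0.079 and 0.25 without 5-Aza-CdR replicate 2 and combination replicate 2. Of the SNU398 arrays, combination replicate 1 and 5-Aza-CdR replicate 2 left JAK-STAT genes at 0.041 and 0.048, and combination replicate 2 left MHC class II genes at 0.16. With the second pairs of HCT116 and HL60 left out, sensing, JAK-STAT, MHC class I and NF-kappaB genes stood at 0.039, 0.079, 0.074 and 0.074, and MHC class II, cancer-testis, immediate early and ribosomal genes at 0.16, 0.028, 0.10 and 0.034.

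For the average, calls ended without HCT116 5-Aza-CdR replicate 1 for sensing, JAK-STAT, MHC class II and cancer-testis genes (adjusted p = 0.11, 0.57, 0.18 and 0.75), and without HCT116 combination replicate 2 for the same lists (0.061, 0.14, 0.061 and 0.40) and metallothioneins (0.061). They ended without HL60 5-Aza-CdR replicate 1 for these 5 lists (0.14, 0.14, 0.48, 0.062 and 0.063) and immediate early genes (0.19). Without HL60 combination replicate 1 and 5-Aza-CdR replicate 2 they ended for JAK-STAT (0.42 and 0.39), metallothioneins (0.87 and 0.93), immediate early genes (0.40 and 0.12) and ribosomal proteins (0.87 and 0.20). They also ended without HL60 5-Aza-CdR replicate 2 for cancer-testis genes (0.086) and without HL60 combination replicate 2 for MHC class II genes (0.15). Without SNU398 combination replicate 1 they ended for JAK-STAT, MHC class II and metallothionein genes (0.23, 0.12 and 0.14). The same held without SNU398 5-Aza-CdR replicate 1 for metallothioneins (0.081), 5-Aza-CdR replicate 2 for JAK-STAT (0.21) and combination replicate 2 for immediate early genes (0.0506). With the second pairs of HCT116 and HL60 left out the cancer-testis call ended (0.15). Adjusted over the list alone on the pair differences, 4 MHC class I, 2 NF-kappaB, 3 sensing, 1 cancer-testis, 2 JAK-STAT, 1 MHC class II and 2 immediate early genes rose, against 0 over all genes. Heat shock proteins (0.17, adjusted p = 0.030), histones (0.15, adjusted p = 0.025) and oxidative phosphorylation genes (0.12, adjusted p = 0.015) were called on the pair differences only, with adjusted p of 0.11, 0.34 and 0.66 with an estimated correlation. In HCT116 ribosomal proteins were called only there (0.21, adjusted p = 0.049; 0.78 with an estimated correlation).

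Lists that camera called in no line and not in the average were those of retrovirus-derived and placental genes, DNA methylation enzymes, histone silencing, histone demethylases, hypoxia, iron and ascorbate, p53 targets, integrated stress, sterol synthesis, apoptosis, silenced and imprinted genes, liver, mesenchymal and lymphocyte markers. The test and the median differed in sign for MHC class II in HCT116 (median -0.07, mean 0.05, test upwards), cancer-testis genes in HL60 (median -0.01, mean 0.01, test downwards) and histones in HL60 (median 0.12, mean 0.02, test downwards). Lymphocyte markers differed so in HCT116 (median 0.03, mean -0.01, test downwards) and in HL60 (median -0.02, mean 0.03, test upwards). With medians and means within 0.05 of 0, the same held for p53, sterol, apoptosis, colon and myeloid lists in SNU398. On average over the lines it held for DNA methylation, demethylase, mitotic, integrated stress, sterol and lymphocyte lists. None of these was called.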
